A study of Homo sapiens with 16 samples.

How the data were processed

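The experiment measured gene expression in KG-1, a human acute myelogenous leukaemia cell line, with 2-colour microarrays. Cells received water extracts of the medicinal fungus Cordyceps sinensis at 20 µl/ml or no extract, and were harvested on day 4, per the labels' protocols. Total RNA was purified and labelled with Cy5 and Cy3 using a dendrimer labelling kit, per the labels' protocols. The design was a double loop: 16 arrays, in 2 loops of 8, joined 8 RNA samples, and each RNA sample was hybridised to 4 arrays, 2 times in each dye. The labels call these 4 arrays technical replicates.

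The deposited values are log2 ratios of the 2 channels. No scanner, image software, background correction or normalization is given in the sources used here, and the unit was read from the values themselves: they lay on both sides of 0, had a ceiling at 16.61, and were unusually often equal to the log2 of a ratio of small whole numbers. In the deposited table, 1547 log2 values equalled, to 3 decimals, the log2 of a ratio of whole numbers up to 10, against a mean of 473 at values shifted slightly to either side. Which dye was the numerator is not stated, and the sign of a value therefore names no RNA sample.

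Before any test, the text of the 16 sample columns was compared. The columns were identical on 32448 of 32448 rows, missing entries included, in each of the 120 pairs of columns. They were counted as 1 array. Whether the repetition arose in the deposit or in the making of the table used here is not known. The column was not assigned to any of the 16 arrays, since no label tells which one it is. The comparisons planned before the data were examined were limma fits of the loop at an adjusted p threshold of 0.05. They covered each extract against untreated cells, the repeated Qinghai sample against its first preparation, Qinghai against Tibet, the parts of the herb against one another, and 21 gene lists. None was run, because identical arrays leave nothing to fit. No p-value between conditions is given for this reason, and the rule fixed for choosing named genes had nothing to act on. On slide 4 the labels disagree on the Cy3 sample (QFB in the source name, QCS2 in the title and treatment text), and on slide 8 the Cy3 treatment text names TW where title and source name give the control. Neither disagreement affects a value here.

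What follows describes the 1 distinct column, by methods chosen after the data were seen. Spots were named from the platform's gene table. It gave 1 symbol for 22064 spots, several for 888 and none for 9496. Symbols were updated through gene identifiers to those of GRCh38.p14, which left 21628 spots with 1 human gene, for 4842 genes. Blocks of 676 spots in row order were inferred from the 4 most often printed genes, whose spots recurred at that period in 97.9% of cases. Each value had its block's median subtracted. A clone is a spotted DNA with its own accession in the platform's table. Clones printed 4 times numbered 5313, and 5172 of them had all 4 values. Only these 5172 could be called displaced. The 164 clones printed more than 4 times were left out, and so were spots without an accession. A clone was called displaced where its 4 centred values had the same sign and each exceeded 1 on the log2 scale, which is 2-fold. A limit of 0.8 was looked at first and was replaced by 2-fold after its counts had been seen. All displaced clones among the 5172 are named. The count was set beside 1000 shuffles of spots and 1000 shuffles of pairs of spots among clones. Gene values were medians over all spots of a gene. A list's median, taken relative to that of all genes, was ranked among 10000 random lists of the same size. Random lists were not matched on expression, since channel intensities were not used here. Spots are repeats within 1 array, so their spread covers error within that array only, position on the slide included. Ratios without intensities also leave the signal behind each value unknown.

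The displacement rule was tested on simulated data with the layout of the 5313 clones: 200 of 200 clones changed by 4-fold were recovered, with 0 false calls. The simulated spots had normal errors with the median spread of the real clones, so noisier clones are not covered. At that spread a 4-fold change lies far beyond the limit and an unchanged clone far short of it. This outcome was therefore near certain in advance, and changes closer to 2-fold were not simulated. Of 300 simulated random lists, 5.0% lay outside the central 95%. These lists were drawn at random from independent values, so a share near this was fixed in advance. Lists of genes that vary together were not simulated. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Alternatives were other centrings, leaving out values at the ceiling, other fold limits and leaving out each of the 4 copies. Columns of values belonging to no sample numbered 0. Scanner files were not used here.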

Results

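The series was built to compare 6 water extracts of Cordyceps sinensis in KG-1 cells, a human acute myelogenous leukaemia line. The extracts came from 2 places, Qinghai and Tibet, and from 3 preparations of the herb: the intact herb (QCS and TCS), the fruiting body (QFB and TFB) and the host worm (QW and TW). The intact Qinghai extract was used for 2 RNA samples, QCS1 and QCS2, as an internal control, and 1 RNA sample came from untreated cells. The labels describe 16 arrays, each with a different pair of these 8 RNA samples.

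The values did not allow any of these comparisons. The 16 sample columns held the same value on every one of the 32448 spots, so that 0 rows differed between any of them. Arrays of 16 different RNA pairs cannot agree to the last digit, and the table was therefore counted as 1 array of unknown RNA pair. No gene can be called higher or lower after any extract from these values, none can be said to be unaffected, and QCS1 could not be set against QCS2. The questions of how an extract differs from no extract, Qinghai from Tibet, and fruiting body from host worm stayed unanswered. The measurements below describe that 1 array. A positive value means more signal in the numerator channel, and neither the RNA sample nor the dye in that channel is known.

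The array gave a log2 ratio for 31633 spots and none for 815 spots (2.51%). Most spots differed little between the channels: 83.2% lay within 2-fold of a ratio of 1. The median was 0.16, the lower quartile -0.24 and the upper quartile 0.57 on the log2 scale. Values above 1 numbered 3697 and values below -1 numbered 1437. A ceiling of 16.61 held 202 spots, while the next highest value was 7.52. The spots at the ceiling are among the values above 1. All counts here were taken before centring and include the spike-in control spots described below.

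The ratios changed with position. Block medians ran from -0.58 in block 12 to 0.74 in block 45. The mean block median was -0.19 over blocks 1 to 16, 0.03 over blocks 17 to 32 and 0.46 over blocks 33 to 48. Within each run of 4 consecutive blocks the first was above the fourth, in 12 of 12 runs, with means of 0.33 and -0.14. For scale, the interval between the quartiles of block-centred clone means was 0.44, which is a narrower kind of measure than a full range. No normalization for position is visible in these values, and gene values are given after subtraction of block medians.

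**Figure D1:**
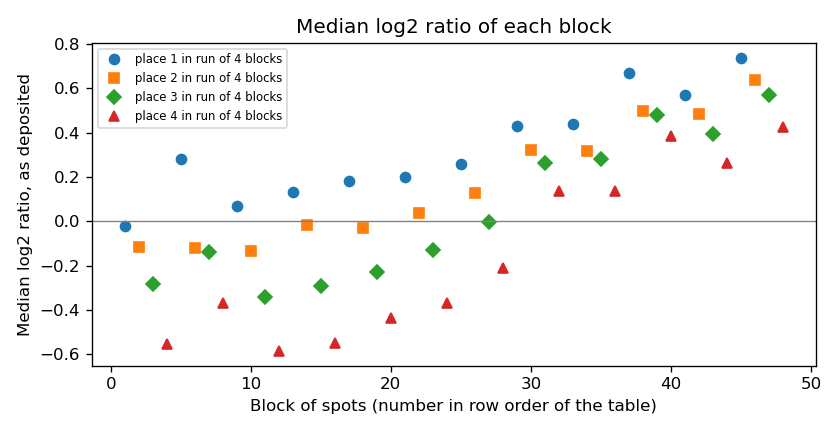
Median log2 ratio as deposited (vertical axis) of each of 48 blocks of spots in row order (horizontal axis), with symbols for the place of a block in its run of 4. Medians rise from the first blocks to the last, up to 0.74, and the first of each run of 4 lies above the fourth.

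The 4 most often printed genes carried symbols known from Arabidopsis genes that are printed on human arrays as spike-in controls, and their identifiers matched no human gene. NAC1 had a median log2 ratio of 5.40 over 90 values, XCP2 4.44 over 95 and PRK 3.34 over 96. The other gene, TIM, had a median of 0.35 over 95 values, with quartiles of -0.03 and 0.77. NAC1 exceeded 1 in 86 values, XCP2 in 91 and PRK in 92, against 10 for TIM. The controls drifted in the same direction as the rest of the slide. From blocks 1 to 16 to blocks 33 to 48 the TIM median went from 0.07 to 0.91 and the PRK median from 2.91 to 3.78. The NAC1 median went from 4.88 to 5.91 and the XCP2 median from 4.04 to 4.80. Each rise was larger than that of the mean block median, from -0.19 to 0.46. The amounts of these RNAs added to each channel are not given in the sources used here.

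Of the clones, 5313 were printed 4 times, as 2 pairs of spots in distant blocks. The median SD of the 4 block-centred spots of a clone was 0.19 on the log2 scale. Across the 5172 complete clones, the mean Spearman correlation was 0.53 between spots of the same pair and 0.47 between spots of different pairs. Clones are not independent replicates, and these correlations describe agreement within the array.

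Of the 5172 clones printed 4 times and with all values, 29 were displaced by more than 2-fold in all 4 spots. Of these, 27 lay on the positive side and 2 on the negative. Shuffling pairs among clones gave a mean of 1.72 positive clones, with a highest count of 8 in 1000 shuffles, and a mean of 0.10 negative clones, with a highest count of 2. None of these shuffles gave 27 positive clones, and 2 of the 1000 gave 2 negative clones. The shuffles break the link between the pairs of a clone, whose spots correlated at 0.47. A count above the shuffles therefore shows only that spots of the same DNA agreed. It does not show that the clones differed between RNA samples. With array median centring in place of block centring, the split was 32 positive and 9 negative clones, and 19 of the 29 clones were called on the same side. With values as deposited it was 65 and 2, with 23 of the 29 on the same side. All 29 clones are named in order of the smallest of their 4 values, since the naming rule fixed beforehand needed a comparison.

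The positive clone with the largest smallest value carried FREM2, an extracellular matrix protein, at a mean of 2.67 ± 0.69 (SD, n = 4 spots). UGT2B4, a glucuronosyltransferase of the liver, followed at 1.99 ± 0.13 and LIPE, the hormone-sensitive lipase, at 2.11 ± 0.35. GRM3, a metabotropic glutamate receptor, stood at 1.99 ± 0.58, and TTBK1, a kinase of tau and tubulin, at 1.92 ± 0.29. TGFB2, a secreted growth factor, stood at 1.73 ± 0.15. POLM, a DNA polymerase of end joining, stood at 1.85 ± 0.64, and MS4A1, which encodes the B cell antigen CD20, at 1.77 ± 0.34. ELAPOR1 stood at 2.56 ± 1.24, with pair means of 3.63 and 1.49. DHODH, an enzyme of pyrimidine synthesis, stood at 1.70 ± 0.41, and BMPR2, a receptor of bone morphogenetic proteins, at 1.76 ± 0.39. AOC2, an amine oxidase, stood at 1.72 ± 0.45, SGSH, a lysosomal sulfatase, at 1.69 ± 0.38, and DENR, a translation factor, at 1.38 ± 0.33.

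The other 13 positive clones, GPC5 to TRIB1, had smallest values of at most 1.13. GPC5, a glypican, had a mean of 1.90 ± 0.97 (SD, n = 4 spots) and AASS, an enzyme of lysine breakdown, 2.19 ± 1.15. LAMC1, a laminin chain, stood at 1.33 ± 0.21, SGCB, a sarcoglycan, at 1.67 ± 0.47, and CCM2L at 1.74 ± 0.49. PCYT1B, an enzyme of phosphatidylcholine synthesis, stood at 1.47 ± 0.40, KIF3A, a kinesin motor, at 1.54 ± 0.67, and MALL at 1.21 ± 0.17. MOB3C stood at 1.37 ± 0.33, but its mean as deposited was 0.88, under the 2-fold limit, so its call rests on the centring. The clock gene PER1 stood at 1.74 ± 0.73, and IL6ST, the shared receptor chain of the interleukin 6 family, at 1.48 ± 0.72. TTYH1 stood at 1.29 ± 0.29 and TRIB1, a pseudokinase, at 1.26 ± 0.26. On the negative side, RNASE1, a secreted ribonuclease, had a mean of -1.96 ± 0.15, and DSG3, a desmosomal cadherin, -3.05 ± 1.94. The pairs of DSG3 disagreed, at -4.73 and -1.37.

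**Figure D2:**
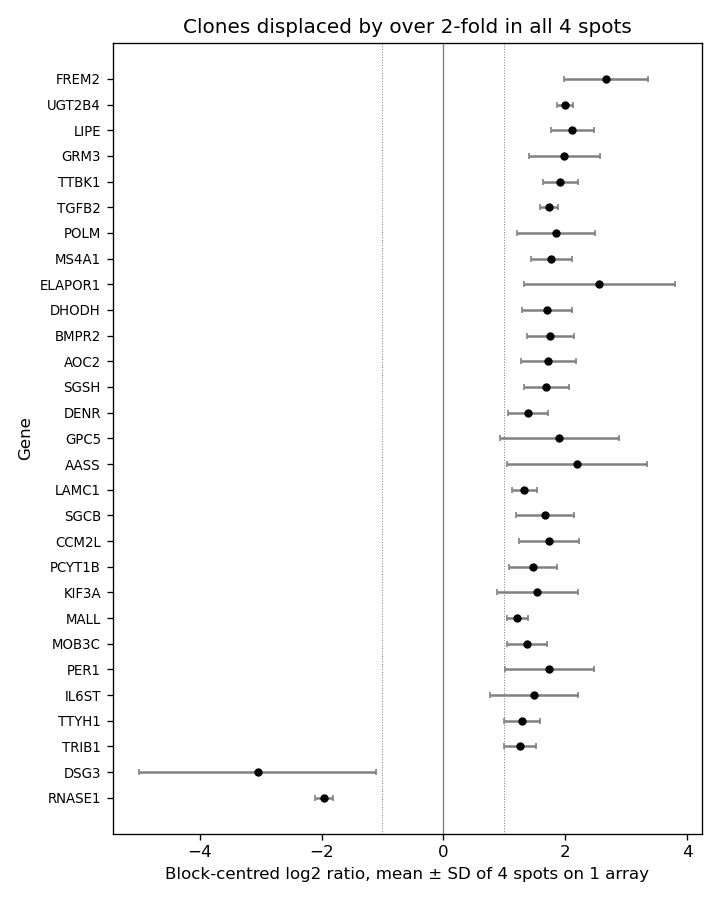
Block-centred log2 ratio (horizontal axis), as mean ± SD of 4 spots on 1 array, of the 27 positive and 2 negative displaced clones (vertical axis, gene names). Dotted lines mark 2-fold; RNASE1 at -1.96 and UGT2B4 at 1.99 have small spreads, and DSG3 has the widest.

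Gene lists fixed before the data were examined were set beside random lists, whose genes are drawn independently. Members of a real list may vary together, which the random lists do not cover. Of 21 lists, 20 had at least 5 measured genes, and 1 of these 20 had a median outside the central 95% of random lists, against 1 that chance gives. That list was the cell cycle genes, with a median of -0.15 relative to all genes, at percentile 1.62. Of its 22 measured members, 14 lay below the median of all genes and 8 above, and 0 were displaced. TK1, thymidine kinase, was at -0.46 with an SD of 0.24 over 4 spots, and TYMS, thymidylate synthase, at -0.40 with an SD of 0.19. The 8 above included the inhibitor CDKN1A at 0.82 with an SD of 0.59. They also included AURKA at 0.39 with an SD of 0.14 and CDC25B at 0.39 with an SD of 0.15. The list's position did not hold with values as deposited (-0.04) or with row and column centring (-0.11), where it lay inside the central 95%. Of the 20 lists, 5 had the other sign with values as deposited and 4 with row and column centring, so no direction is read from a list inside the band. Other lists lay just inside the band. Among them were oxidative phosphorylation at percentile 2.67, erythroid and megakaryocyte markers at 3.33, and epithelial and fibroblast markers at 96.1. The count outside the band therefore does not show that the lists behaved like random ones. Members named here were chosen after their values were seen.

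Lists for immune and inflammatory responses lay inside the range of random lists. Cytokines and chemokines had a median of 0.02 over 12 genes, at percentile 56.4. NF-kB and Toll-like receptor genes had 0.04 over 13 genes, at percentile 66.2, and interferon-stimulated genes 0.05 over 17 genes, at percentile 69.9. IL1A was at 1.23 with an SD of 0.31, TNFAIP3 at 0.40 with an SD of 0.07, and IL1B at -0.29 with an SD of 0.15. Apoptosis genes had a median of -0.01 over 17 genes, adenosine and purine genes -0.12 over 15, and polyadenylation factors -0.03 over 10. Oxidative stress genes had -0.02 over 13 genes, cholesterol genes -0.02 over 12, antigen presentation -0.15 over 9, and immediate early genes -0.05 over 10.

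Oxidative phosphorylation genes had a median of -0.13, with 19 of 24 members below the median of all genes, at percentile 2.67. Heat shock and unfolded protein genes had -0.15 over 14 genes, at percentile 4.70. Glycolysis and hypoxia genes had -0.12 over 13 genes, and ribosomal protein genes -0.03 over 32. Metallothioneins had 1 measured gene and were not ranked.

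Markers of cell types also lay inside the band with block centring. Monocyte, macrophage and dendritic markers had a median of -0.22 over 7 genes, at percentile 3.50, with 5 of the 7 below the median of all genes. S100A9 was at -0.58 with an SD of 0.19 and FPR1 at 0.38 with an SD of 0.91. Myeloblast and progenitor markers had -0.06 over 9 genes, 5 of them below the median of all genes. The transcription factor MYB was at 0.69 with an SD of 0.14. The granule genes differed: MPO was at 1.04 with an SD of 1.37, ELANE at 1.27 with an SD of 0.59 over 3 spots, and PRTN3 at -0.36 with an SD of 0.15. Erythroid and megakaryocyte markers had -0.18 over 11 genes, at percentile 3.33, and lymphoid markers, which include the displaced MS4A1, 0.05 over 13 genes, at percentile 68.6. Epithelial and fibroblast markers had 0.22 over 12 genes, at percentile 96.1. Erythroid and megakaryocyte markers lay outside the central 95% with values as deposited (-0.33), and with row and column centring so did monocyte (-0.28) and epithelial and fibroblast markers (0.29).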

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

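All alternatives here were chosen after the data were seen. The alternatives set before the data were examined (filters on missing values, array scaling, the dye term, the reading of slide 4, other priors, each array left out, RNA samples or arrays as the unit, the part of the herb as a term, treated RNA samples left out of their mean, other list tests) were not run, because the 16 identical columns give no fit to vary. No paired analysis was possible because the columns of all replicates were identical. With values as deposited, 65 clones were positive, the median spread of 4 spots was 0.33 and the correlation between distant pairs 0.54. With array median centring, 9 clones were negative, with the same 0.33 and 0.54, since 1 constant for all spots moves neither. A limit of 1.5-fold gave 111 positive and 14 negative clones, a limit of 3-fold gave 5 and 1, and the first limit looked at, 0.8 on the log2 scale, gave 45 and 6. Requiring 3 copies asks less of a clone: without copy 1, 2, 3 or 4 the positive clones were 44, 39, 47 and 57 and the negative clones 5, 9, 6 and 12. Centring rows and columns within blocks, and leaving out values at the ceiling, kept counts within 1.5 times, and the spread and correlation close to their values (0.192 and 0.447 with rows and columns centred). Of the 20 lists, 18 kept their side of the 95% band with values as deposited, 17 with row and column centring and 20 without values at the ceiling. The cell cycle list came inside the band with both of these other centrings. The median of all genes was 0.12 as deposited and -0.02 with block centring, and list values are relative to it. The single array and the unknown intensities limit every value here.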

Other observations

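The tests and the pair of lists in this part were chosen after the results were seen. Markers of epithelial cells and fibroblasts had a median 0.25 above that of ribosomal proteins on the log2 scale (12 and 32 genes), a pair picked from the 21 lists by its values, with no test because genes on 1 array are not replicates. The gap was 0.11 with values as deposited and 0.31 with row and column centring. FN1 was at 0.99 and COL1A2 at 0.74 relative to all genes, with SDs of 0.88 and 0.99 over 4 spots, while ACTA2 was at 0.40 with an SD of 0.07. KRT18 and LUM lay on the other side, at -0.37 and -0.32.

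Most displaced clones lay on the positive side, 93.1% of 29, against 97.0% with values as deposited and 78.0% with array median centring. Drift within blocks stayed open: after rows and columns were centred too, 92.0% were positive, but that centring hardly moved the spread or the correlation of spots and so decides nothing. A candidate explanation is weak signal in 1 channel, where a small background difference gives a large ratio, and the values do not settle it. Spots at a ratio of whole numbers up to 10 were taken as weak, an assumption that was not checked because intensities were not used here. They made up 5.56% of spots in positive displaced clones and 3.64% in clones not displaced, a difference of 1.91 percentage points (95% bootstrap interval over clones -2.05 to 6.75). Values shifted slightly, which meet such ratios by coincidence, gave 0.77% and 1.61%. The 2 sets of clones were also unlike by selection. A displaced clone can hold no spot at a ratio of exactly 1, which was counted as weak and held 275 spots of the array. The comparison of shares therefore cannot decide. This form of the test replaced an earlier one after the result of the earlier one was known.

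The earlier form took 728 clones with exactly 1 weak spot, which was missing, at the ceiling or at such a ratio, and 4474 clones with none. The median of the other spots was 0.08 higher in the clones with a weak spot (95% bootstrap interval 0.03 to 0.12), which does not show whether a few of them were displaced. In their other 3 spots, 2.20% of these clones were beyond 2-fold on the positive side and 0.41% on the negative. In clones with no weak spot, with each spot left out in turn, these shares were 0.83% and 0.067%. The positive share was 1.37 percentage points higher in clones with a weak spot (95% bootstrap interval 0.36 to 2.58), and the negative one, from 3 clones, was higher too. Positive clones outnumbered negative ones in both sets. Of the clones beyond 2-fold on either side, 84.2% were positive with 1 weak spot and 92.5% with none. The share of 84.2% rests on 16 positive and 3 negative clones. Whether the lean to the positive side differed between the sets was not tested, so nothing is concluded from these shares.

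The spread of 4 spots was wider in positive displaced clones, with a median SD of 0.40 against 0.19 in clones not displaced. No biological explanation was tested, because the RNA pair is unknown.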
